A study of Mus musculus with 12 samples.

How the data were processed

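RNA was taken from frozen mouse kidneys with Trizol and a column kit, and 1 µg of total RNA went into libraries made with standard Illumina protocols, per the labels' protocols. The 12 samples (ICR strain, 8 weeks old) were placed in 4 groups of 3 by the description in their labels, and replicate numbers came from their titles. The labels give neither sex nor a busulfan dose, and do not say whether replicates are separate animals. Per the submitters' processing notes the authors used Bowtie 0.12.2 and the mm10 build; the counting tool, the annotation and the strand setting are not given in the sources used here.

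The authors deposited a single table of FPKM values, 1 column per library, rounded to 2 decimals, with Entrez gene identifiers and symbols for 21004 genes, per the file headers. FPKM values are scaled to the mapped total of each library, so they keep no absolute depth. Relative depth was estimated from the steps between low values in 232 genes detected in 2 to 6 libraries and ran from 0.917 to 1.087. A step is the smallest difference a gene can show, and the rounding to 2 decimals limits low values further. Of the symbols, 26 were stored as dates and were restored through their Entrez identifiers, and 1 symbol then repeated was kept once, by the higher mean. Of the identifiers, 20841 were found in the RefSeq gene table of GRCm38.p6, from which coordinates were taken. Transcript lengths and GC content came from GENCODE release M21 and covered 98.6% of the tested genes. Xist and the mitochondrial genes are not analysed here.

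Genes with an FPKM of at least 1 in at least 3 libraries were kept, which left 12281. Values were transformed to log2(FPKM + 1), so a log2 change understates the change of low genes. One mean per group was fitted to all 12 libraries with limma 3.58.1 (R 4.3.3, trend option), so that the groups shared an estimate of the spread. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no fold threshold. The 5 comparisons were busulfan against control, busulfan plus L.J. against busulfan, L.J. alone against control, busulfan plus L.J. against control, and the interaction (busulfan plus L.J. minus L.J. alone, less busulfan minus control). The unit was not a count, so no count model was used.

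Before the data were examined, 47 gene lists were fixed, covering kidney cell types, tissues a dissected kidney can carry, and pathways. The 42 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. With an estimated correlation 0 lists were called in any comparison, and fry called 1, in busulfan plus L.J. against busulfan. Per-library medians of a list are against the mean of the 3 control libraries. Named genes followed a rule fixed at the same time: the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, leaving out predicted and unnamed genes; the 3 smallest p in a direction without calls; up to 4 members of each called list; and 8 genes chosen in advance. For the interaction the rule was used without the overlap condition.

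The share of genes moved back was compared with 1000 simulations in which busulfan plus L.J. libraries had the busulfan group's means. The method was tested on simulated data over 12281 genes, with 100 changed at each size. For busulfan against control it recovered 88% of changes of 1 on the log2 scale and 99% of changes of 2, and for the interaction 72% and 97%. Each simulated change was the same in all busulfan libraries, and the noise was drawn separately for each gene. No simulated library stood apart from its group, as busulfan 3 did, so these rates need not hold for these data. The alternatives fixed beforehand were a pseudocount of 0.1, no filter, quantile normalization, library weights, the replicate number as a block, only the groups compared, and each library left out in turn. A correction for transcript length and GC content, busulfan 3 left out of the fits for the comparisons without it, a simulation with the busulfan group's own spread, and the simulated share over as many genes as were called, were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.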

Results

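Gene expression was measured by RNA sequencing in kidneys of 8-week-old mice of the outbred ICR strain. The 12 libraries formed 4 groups of 3: control, busulfan, busulfan plus L.J., and L.J. alone. Busulfan is an alkylating drug that crosslinks DNA. L.J. is named by these letters in the sample descriptions and appears as Lu in the sample titles. Both groups given it carry 10 mg/kg in their labels. The design text of the series speaks of FMT in place of L.J., and none of these terms is explained in the labels, so what was given in the L.J. groups is uncertain. The series title names the question, which is whether L.J. rescues adverse effects of busulfan on the kidney. The values were FPKM, fragments scaled to gene length and to the mapped total of a library, for 21004 genes, of which 12281 passed the filter on low values. The FPKM sums per library ran from 481937 to 541844. Absolute depth is unknown, and steps between low values put the relative depths within a ratio of 1.19. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

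The libraries of the busulfan group were not alike. On the first principal component, which carried 41.8% of the variance, busulfan 1 and busulfan 2 scored -40.4 and -47.3, while busulfan 3 scored 10.5 and the 9 libraries of the other groups scored between 1.9 and 16.9. The Spearman correlation across genes was 0.987 between busulfan 1 and 2, 0.954 between 1 and 3 and 0.950 between 2 and 3. Pairs within the other groups lay between 0.976 and 0.989. Busulfan 3 also had a trend of expression with transcript length (Spearman -0.515 across genes, against -0.136 to 0.216 in the other libraries) and with GC content (0.425, against -0.188 to 0.248). Its relative depth of 0.917 was the lowest of the 12.

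**Figure D1:**
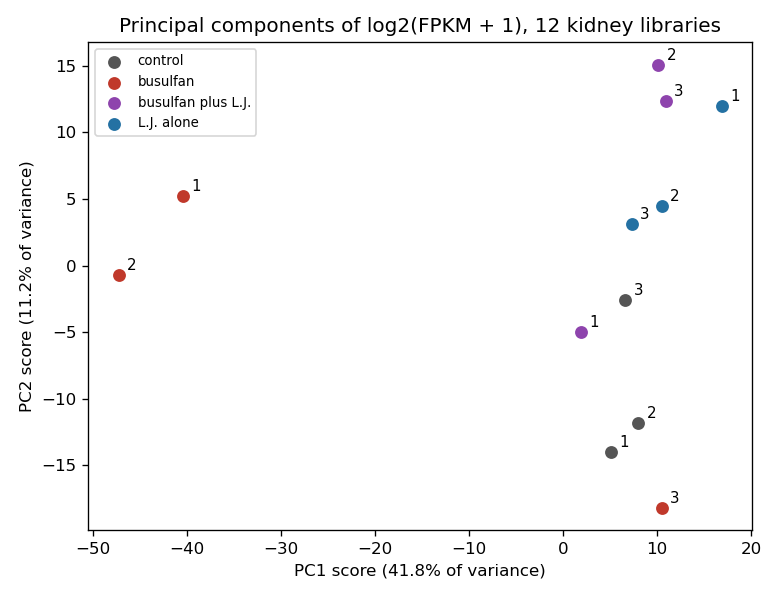
Scores of the 12 libraries on the first 2 principal components of log2(FPKM + 1), with PC1 on the horizontal and PC2 on the vertical axis, colours for groups and digits for replicate numbers. Busulfan 1 and 2 sit at -40.4 and -47.3 on PC1, and busulfan 3 at 10.5, among the other groups.

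The first comparison set busulfan against control and asked what the drug did to the kidney. Genes of glutathione conjugation were among those that rose most. The transferase gene Gsta1 rose from 2.72 ± 1.37 to 10.4 ± 4.06 FPKM (mean ± SD, n = 3; log2 change 1.61, SE 0.34, limma adjusted p = 0.0472), Mgst1 from 25.8 ± 1.53 to 85.8 ± 47.8 (adjusted p = 0.0486), and Gsta3 rose too (log2 change 1.05, SE 0.23, adjusted p = 0.0492). Akr1c14, an aldo-keto reductase of steroid metabolism, fell from 214 ± 19.2 to 50.5 ± 43.3 FPKM (log2 change -2.38, SE 0.41, adjusted p = 0.0364). Its values in busulfan 1, 2 and 3 were 20.8, 30.4 and 100.1 FPKM. In all, 177 genes changed, 89 higher and 88 lower, and each of them had no overlap between the 3 libraries of the groups. Of the 12281 tested genes 2705 had no overlap, where 10% is the share by chance.

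Further genes that rose in this comparison were Wfdc17 (log2 change 1.25, SE 0.15, adjusted p = 0.0138), the plasma cell gene Mzb1 (1.29), Zfp868 (1.28), the kinase gene Nuak2 (1.21), the cytochrome P450 gene Cyp2a5 (1.18), the leukotriene C4 synthase gene Ltc4s (1.15) and the cytokine-signalling inhibitor Socs2 (1.14). Genes that fell included Zbtb8b (-1.50), the ether lipid synthesis gene Agps (-1.42), the phospholipid flippase gene Atp11a (-1.41), Csgalnact1 (-1.40), Olfr1033 (-1.23), the collagen lysyl hydroxylase gene Plod2 (-1.14), Tsga10 (-1.02), the transcription factor gene Etv1 (-0.997) and the lipid hydrolase gene Abhd2 (-0.99, SE 0.11, adjusted p = 0.0137). Gsta1 and Gsta3 have close paralogs that can share reads, so their values are uncertain in that respect. Several of these genes were shifted less in busulfan 3: Agps was 15.6, 16.8 and 40.6 FPKM in busulfan 1, 2 and 3 against 60.9 ± 1.78 in control. Others were shifted alike, with Wfdc17 at 2.76, 3.03 and 2.80 against 0.63 ± 0.17, Zbtb8b at 8.48, 7.38 and 7.94 against 24.5 ± 4.82, and Abhd2 at 12.1, 14.9 and 16.4 against 29.5 ± 1.63. A gene passes more easily where busulfan 3 agrees, so the calling itself favours such agreement. Busulfan 3 also had lower values for longer transcripts, and Abhd2 has a long one (6877 bp). So do Atp11a (7549 bp), Agps (7359 bp) and Etv1 (6576 bp) among the falls, while Ltc4s (716 bp) and Gsta1 (875 bp) among the rises have short ones. Of the other falls, Akr1c14 (3183 bp) and Csgalnact1 (3943 bp) are shorter. The length trend may therefore have helped several of these genes to pass. After a correction for length and GC content few genes were called, as given below.

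**Figure D2:**
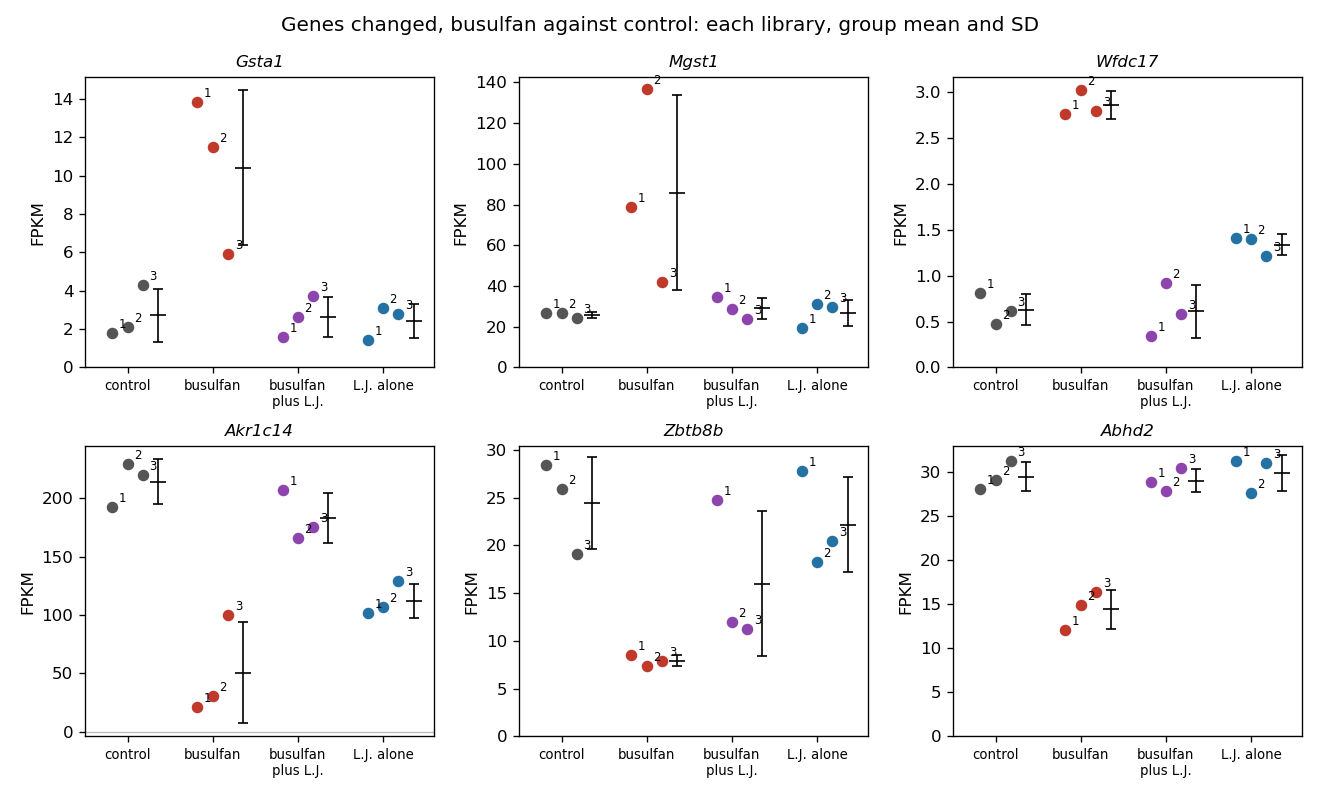
FPKM of 6 genes that changed between busulfan and control, in each library (points, digits for replicate numbers) by group, with the group mean and SD as black bars (n = 3). Wfdc17, Zbtb8b and Abhd2 had similar levels in the 3 busulfan libraries, while Akr1c14 was 20.8, 30.4 and 100.1 FPKM in busulfan 1, 2 and 3.

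In the GRCm38.p6 assembly, Gsta1 (Entrez gene 14857) lies on chromosome 9 from 78230669 to 78242683, Wfdc17 (100034251) on chromosome 11 from 83704056 to 83706269, Akr1c14 (105387) on chromosome 13 from 4048991 to 4090560 and Abhd2 (54608) on chromosome 7 from 79273266 to 79361601. All 4 are annotated as protein-coding genes, and the values are per gene, over its exons.

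The gene lists fixed beforehand gave 10 calls in this comparison, 6 up and 4 down. Ribosomal protein genes rose as a list, with a median log2 change of 0.60 over 30 members (camera adjusted p = 3.2e-13; adjusted p = 0.783 with an estimated correlation). Of these 30, 5 rose over all genes and 28 adjusted over the list alone, Rps15 among them (379 ± 13.8 to 632 ± 145 FPKM, adjusted p = 0.0428), with Rpl18 (0.62) and Rpl23 (0.72). Glutathione S-transferases rose as a list (median 0.62, camera adjusted p = 1.4e-04; adjusted p = 0.783 with an estimated correlation), with 3 of 18 higher over all genes, and 12 higher and 1 lower adjusted over the list alone. Markers of the collecting duct were higher too. Intercalated cell genes had a median of 0.79 (camera adjusted p = 2.3e-05; adjusted p = 0.783 with an estimated correlation), with 0 of 12 past the threshold over all genes and 10 adjusted over the list alone; the ammonia channel gene Rhcg was 26.9 ± 2.42 in control and 51.6 ± 15.6 in busulfan (adjusted p = 0.0567). Principal cell genes had a median of 0.46 (camera adjusted p = 0.0139; adjusted p = 0.783 with an estimated correlation), with 2 of 10 higher over all genes, Hsd11b2 (0.75, adjusted p = 0.0428) and the sodium channel subunit Scnn1a (0.89, adjusted p = 0.0492), and 4 adjusted over the list alone. The medians of these 4 lists were 0.22, 0.25, 0.18 and 0.07 in busulfan 3, below those of busulfan 1 (0.64, 0.77, 1.12 and 0.68) and busulfan 2 (0.95, 0.88, 1.18 and 0.80).

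Male-biased kidney genes fell as a list, with a median log2 change of -1.27 over 13 members (camera adjusted p = 5.2e-09; adjusted p = 0.783 with an estimated correlation). Over all genes 0 of the 13 passed, and 9 were lower adjusted over the list alone. The list medians against the control mean were -1.85 in busulfan 1, -2.16 in busulfan 2 and 0.10 in busulfan 3. Kap, the androgen-regulated kidney protein gene, was 10398, 5031 and 50482 FPKM in busulfan 1, 2 and 3 against 42643 ± 9222 in control (log2 change -1.60, SE 0.64, adjusted p = 0.175). It made up 2.13%, 1.03% and 9.32% of all FPKM in these 3 libraries. The organic anion transporter gene Slco1a1 was 28.4, 27.0 and 190.3 FPKM against 271 ± 36.4 (adjusted p = 0.0567). Female-biased genes were not called as a list, and their medians were 0.71, 0.76 and -0.10. The Y-linked gene Ddx3y was 15.03, 13.9 and 8.28 FPKM against 15.4 ± 1.18 in control (adjusted p = 0.313).

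**Figure D3:**
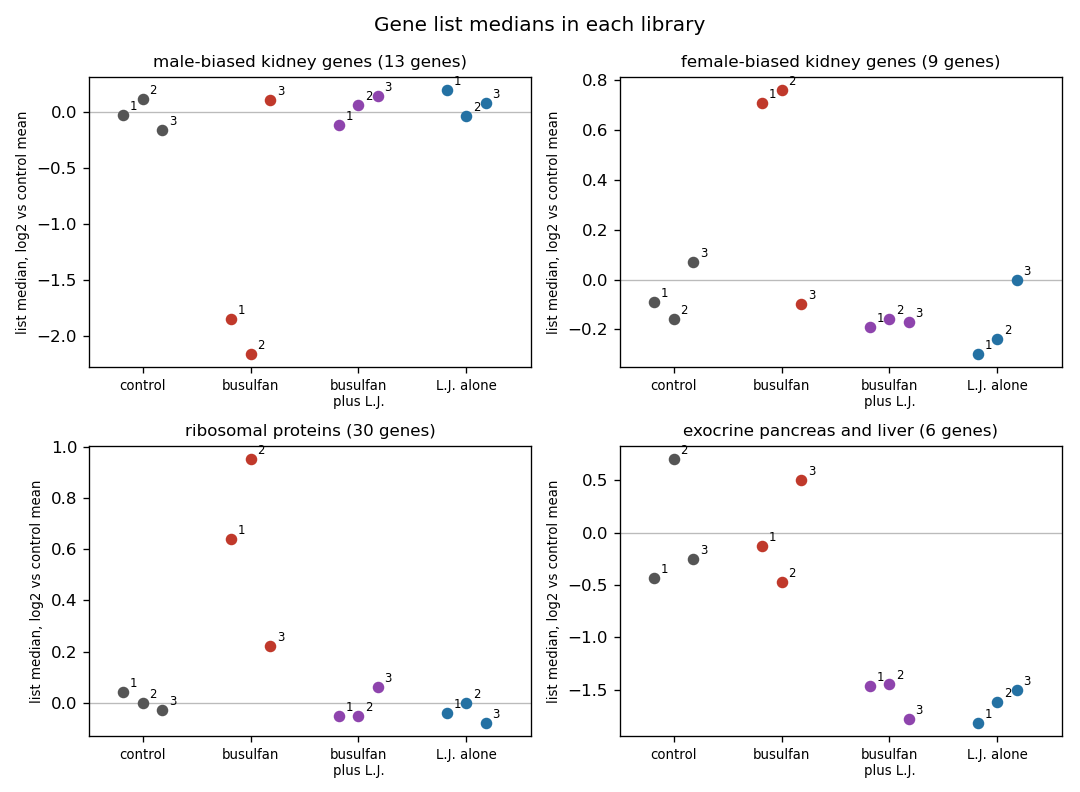
Median log2 difference from the control mean of 4 gene lists (vertical axis) in each library, by group, with digits for replicate numbers. Male-biased genes were at -1.85 and -2.16 in busulfan 1 and 2 and at 0.10 in busulfan 3, and the pancreas and liver list lay between -1.82 and -1.45 in the 6 libraries with L.J.

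The other calls against control were smaller. Distal convoluted tubule genes were higher (median 0.36, camera adjusted p = 0.0460; adjusted p = 0.783 with an estimated correlation), 1 of 10 over all genes and 1 adjusted over the list alone, the kinase gene Wnk4 (0.80, adjusted p = 0.0428). Immediate early genes had a median of 0.42 (camera adjusted p = 0.0229; adjusted p = 0.783 with an estimated correlation), heat shock genes -0.18 (0.00198; adjusted p = 0.783 with an estimated correlation), replication-dependent histones -0.43 (0.0229; adjusted p = 0.783 with an estimated correlation) and endothelial genes -0.21 (0.0415; adjusted p = 0.788 with an estimated correlation). In these 4 lists 0 members passed over all genes, and 3 heat shock genes were lower adjusted over the list alone. Busulfan 3 lay on the other side of control from busulfan 1 and 2 for immediate early (-0.10), heat shock (0.15) and histone genes (0.06). Without it these medians were 0.67, -0.36 and -0.63, and that of distal convoluted tubule genes was 0.68. Of the 10 calls 5 held with every library left out (ribosomal proteins, glutathione S-transferases, principal cell, intercalated cell and male-biased genes), and each of the other 5 was lost without busulfan 1 or busulfan 2. The circadian clock list, not called, had medians of 1.09, 0.98 and 0.20 in busulfan 1, 2 and 3.

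Markers of kidney injury did not pass, and the tubular injury list was not called. The medians of that list nevertheless lay between 0.15 and 0.42 in the busulfan libraries and between -0.02 and 0.04 in control. They lay between -0.04 and 0.25 with busulfan plus L.J. and between -0.18 and 0.12 with L.J. alone. Havcr1 was 2.08 ± 0.09 FPKM in control and 1.96 ± 0.66 in busulfan (adjusted p = 0.822), Lcn2 2.35 ± 1.19 in control and 7.75, 10.7 and 1.30 in busulfan 1, 2 and 3 (adjusted p = 0.443) and Umod 863 ± 206 and 991 ± 284 (adjusted p = 0.663). Of the p53 targets that respond to DNA damage, Cdkn1a was 9.94 ± 0.53 and 23.7 ± 13.7 FPKM (log2 change 1.04, SE 0.32, adjusted p = 0.0971) and Mdm2 13.0 ± 0.50 and 15.9 ± 2.31 (adjusted p = 0.197). The p53 target list was not called, with a median of 0.20 (camera adjusted p = 0.205) and per-library medians of 0.19, 0.46 and 0.01. Without busulfan 3 its median was 0.31, with 6 of 20 members higher over all genes (camera adjusted p = 0.238).

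The count of 177 genes rested on single libraries. Without busulfan 3 it was 3973, with 2979 higher and 994 lower and all 177 included. Without any other library of these groups it was between 0 and 5, and with a correction for transcript length and GC content, added after the trend in busulfan 3 was seen, it was 3. Without busulfan 3 the fall of the male-biased list also passed with an estimated correlation (median -1.96, 13 of 13 members lower, adjusted p = 0.0303 with an estimated correlation). That fit keeps only busulfan 1 and 2 and drops the busulfan library without the fall (median 0.10), so it is not independent support. Quantile normalization gave 503 genes, 181 higher and 322 lower. FPKM values are shares of a total, of which Kap alone took a smaller part in busulfan 1 and 2. With all libraries the median log2 change over all tested genes was 0.083. The split into higher and lower genes thus depended on the scaling, also in the fit without busulfan 3, which used the same FPKM. The lists called without busulfan 3 were 22.

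The comparison of busulfan plus L.J. with busulfan asked whether L.J. altered the busulfan-treated kidney. Of 398 genes that changed, 145 were higher and 253 lower with L.J. added, each without overlap (19.2% of all genes had none, 10% by chance). Akr1c14 rose from 50.5 ± 43.3 to 183 ± 21.5 FPKM (n = 3; log2 change 2.16, SE 0.41, limma adjusted p = 0.0340), Agps from 24.3 ± 14.1 to 64.2 ± 3.09 (1.498, adjusted p = 0.0320) and Ccdc6 from 28.7 ± 8.71 to 81.5 ± 23.0 (1.47, adjusted p = 0.0174). Largest among the falls was Cyp4a14, a fatty acid hydroxylase of the kidney, from 92.1 ± 77.8 to 1.71 ± 0.17 FPKM (-4.06, SE 0.96, adjusted p = 0.0471). Its busulfan value came from busulfan 1 and 2, at 121 and 151 FPKM, with 3.98 in busulfan 3. The neutrophil genes S100a9 (-3.68, adjusted p = 0.0331) and S100a8 (-3.27, adjusted p = 0.0445) fell too, and S100a9 was 32.6, 51.9 and 3.73 FPKM in busulfan 1, 2 and 3.

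Other genes that rose were Atp11a (1.42), the mitochondrial glycerophosphate dehydrogenase gene Gpd2 (1.34), the organic anion transporter gene Slc22a30 (1.32), Slc18a1 (1.22), Tmem86a (1.14), Etv1 (1.10) and the phosphatidylinositol kinase gene Pi4ka (1.01). Of the genes that rose, Agps, Atp11a, Etv1, Gpd2 (5759 bp) and Ccdc6 (5511 bp) have long transcripts, and Akr1c14 (3183 bp) a shorter one. The length trend of busulfan 3 bears on these too, and none was called after the length and GC correction. Falls were also seen for the tyrosine degradation gene Hpd (-3.34), the protease inhibitor gene Slpi (-2.64), the major urinary protein genes Mup2 (-2.37), Mup8 (-2.33) and Mup19 (-2.28), Ggt6 (-1.92) and the apolipoprotein gene Apoa2 (-1.88). The Mup genes are near-identical copies, so reads can be assigned to the wrong member and their separate values are uncertain. Mup2 and Mup8 were also lower with L.J. alone than in control, though not past the threshold. Their falls were thus not particular to the busulfan-treated kidney, and liver transcripts are taken up below.

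Gene lists gave 17 calls, 7 up and 10 down. Ribosomal protein genes fell (median -0.60, camera adjusted p = 2.0e-13; adjusted p = 0.563 with an estimated correlation), 9 of 30 over all genes and 27 adjusted over the list alone, such as Rpl38 (496 ± 131 to 264 ± 4.36 FPKM, adjusted p = 0.0331) and Rps28 (-0.90, adjusted p = 0.0340). Glutathione S-transferases fell (median -0.73, camera adjusted p = 2.4e-06; adjusted p = 0.563 with an estimated correlation), 6 of 18 over all genes and 15 adjusted over the list alone, with Gsta3 at 16.2 ± 3.54 FPKM with L.J. added (-1.53, SE 0.23, adjusted p = 0.0174) and Gstm7 (-1.13). This list was also called by fry, with a false discovery rate of 0.0323. Male-biased genes rose as a list (median 1.29, camera adjusted p = 2.3e-09; adjusted p = 0.563 with an estimated correlation), with 0 of 13 past the threshold over all genes and 12 adjusted over the list alone. Their medians against control in busulfan plus L.J. 1, 2 and 3 were -0.12, 0.06 and 0.14. Without busulfan 3 the rise was 1.92, with 13 of 13 members higher over all genes and adjusted p = 0.0268 with an estimated correlation. As above, this fit drops the only busulfan library in which these genes were not low.

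Lists of the thick ascending limb, distal tubule and collecting duct were lower with L.J. added, and the proximal tubule list was higher. Intercalated cell genes had a median of -0.71 (camera adjusted p = 2.3e-04; adjusted p = 0.563 with an estimated correlation), 2 of 12 lower over all genes and 6 adjusted over the list alone, with Atp6v1g3 (-1.11) and Rhcg (-0.86) past the threshold. Principal cell genes had a median of -0.52 (0.00253; adjusted p = 0.563 with an estimated correlation), 2 of 10 lower over all genes and 4 adjusted over the list alone. Thick ascending limb genes had -0.42 (0.00861; adjusted p = 0.588 with an estimated correlation), with 1 of 12 and 4 adjusted over the list alone, and distal convoluted tubule genes -0.33 (0.0335; adjusted p = 0.588 with an estimated correlation), with 2 of 10 and 2 adjusted over the list alone. Proximal tubule transport genes had 0.22 (0.00148; adjusted p = 0.563 with an estimated correlation), with Slc22a30 higher and 1 other member lower, over all genes and adjusted over the list alone.

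Lists of other tissues moved in the same comparison. The pancreas and liver list fell (median -1.52, camera adjusted p = 0.00382; adjusted p = 0.563 with an estimated correlation), 4 of 6 over all genes and 5 adjusted over the list alone: albumin (Alb) went from 21.4 ± 8.78 to 5.86 ± 1.17 FPKM (adjusted p = 0.0437), with Apoa1 (-1.66), Ttr (-1.41) and Mup3 (-1.78). Adipocyte genes had a median of 0.80 (0.00253; adjusted p = 0.563 with an estimated correlation) with 0 of 11 past the threshold over all genes or adjusted over the list alone, and their medians against control were 2.13, 1.65 and -0.54 in busulfan plus L.J. 1, 2 and 3. Acute phase genes fell (-0.43, 0.0112; adjusted p = 0.563 with an estimated correlation), 3 of 14 over all genes and 4 adjusted over the list alone, the 3 being the fibrinogen genes Fga, Fgb and Fgg, which the liver makes.

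The other calls were neutrophil genes (-0.27, with 2 of 5 lower over all genes and adjusted over the list alone, S100a8 and S100a9), immediate early genes (-0.46, with 2 of 16 and 3 adjusted over the list alone), heat shock genes (0.41, with 1 of 13, Dnaja1, and 3 adjusted over the list alone), replication-dependent histones (0.47, with 2 of 6 and 2 adjusted over the list alone), erythroid genes (0.73, with 0 of 8) and proliferation genes (0.21, with 0 of 13). Each had an adjusted p = 0.563 with an estimated correlation. Of the 17 calls 11 held with every library left out. Those of the pancreas and liver list (median -1.22, camera adjusted p = 0.235) and of acute phase genes (-0.41, 0.274) were lost without busulfan 3, and those of distal convoluted tubule, neutrophil, erythroid and proliferation genes without busulfan 1 or busulfan 2. Without busulfan 3 the count of changed genes was 3867, of which 397 were among the 398, and 25.3% were higher in place of 36.4%. Leaving out any other library of the comparison gave between 1 and 71 genes, the length and GC correction gave 0, and quantile normalization gave 656 with 61.3% higher. The median log2 change over all tested genes was -0.087, so here too the split by direction depended on the scaling.

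For rescue in the sense of the title, the direction of the 177 busulfan-called genes was followed into busulfan plus L.J. All of them, 100%, moved back towards or past control. Both comparisons share the busulfan libraries, so a share above 50% arises without an effect of L.J. on the busulfan group. Simulated libraries without that effect gave 73.4% (66.7 to 79.7 in the central 95% of runs) over the 177 genes with the smallest p of each run, or 83.6% (78.5 to 88.7) with the busulfan group's own spread. Over all genes called in a run (medians of 1126 and 1547) the shares were 69.4% and 76.0%. These simulations took the observed busulfan means as true and drew the noise of each gene separately. They left out the pattern that busulfan 1 and 2 shared over many genes, so their ranges may be too narrow. That the observed 100% lies above them therefore does not decide on rescue. Of the 89 genes higher with busulfan, 59 were among the 253 lower with L.J. added, where independent lists would share 1.83, and of the 88 lower with busulfan, 70 were among the 145 higher, where independent lists would share 1.04. The simulations without an effect shared a median of 0, with the same limits. The simulated value leaves out an effect of L.J. and the value for independent lists leaves out the shared libraries, so part of the excess over the latter may come from sharing.

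Comparisons that share no library are free of that. Across the 12281 genes, the change from L.J. alone to busulfan plus L.J. had a Pearson r of 0.050 (jackknife SE 0.097 over libraries) and a Spearman rho of 0.054 with the change from control to busulfan, and a slope of 0.044 (SE 0.060). Genes are not independent replicates, so these values describe the 4 group means. Leaving out busulfan 1 turned r to -0.003 and leaving out busulfan 3 gave 0.101.

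**Figure D4:**
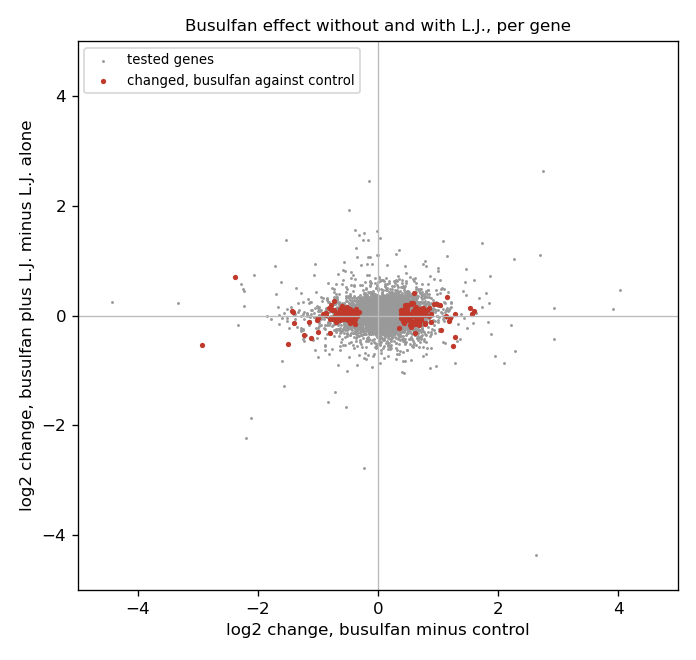
Log2 change of each tested gene with busulfan in the absence of L.J. (busulfan minus control, horizontal) and in its presence (busulfan plus L.J. minus L.J. alone, vertical), with the 177 genes called against control in red. The red genes spread along the horizontal axis and lie near 0 on the vertical axis (r = 0.050 over all 12281 genes).

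The direct test of whether the busulfan effect differed with L.J. was the interaction of both treatments. It called 2 genes, both lower. Wfdc17, a small whey acidic protein family gene, was 2.86 ± 0.15 FPKM with busulfan and 0.63 ± 0.17 in control, but 0.61 ± 0.29 with busulfan plus L.J. and 1.34 ± 0.11 with L.J. alone (n = 3; interaction -1.80, SE 0.21, limma adjusted p = 0.0252). Phlda1 was 11.4 ± 0.89 and 7.04 ± 0.07 without L.J., and 6.88 ± 0.36 and 8.85 ± 0.49 with it (-0.94, SE 0.12, adjusted p = 0.0467). With positive values and not past the threshold were Psme4 (0.75, adjusted p = 0.148), Abhd2 (0.95, adjusted p = 0.148) and the basement membrane collagen gene Col4a3 (0.89, adjusted p = 0.179). At an unadjusted p under 0.05 there were 1437 genes, and without busulfan 3 the adjusted count was 1488. Leaving out any other library gave 0 to 2, and fewer than 2 for all but busulfan plus L.J. 2.

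Of the gene lists, 13 were called for the interaction, 4 up and 9 down. Ribosomal proteins had a median of -0.55 (camera adjusted p = 1.2e-12; adjusted p = 0.817 with an estimated correlation), with 0 of 30 past the threshold over all genes and 15 adjusted over the list alone. Glutathione S-transferases had -0.62 (2.7e-05; adjusted p = 0.817 with an estimated correlation), with 0 of 18 and 5 adjusted over the list alone. Male-biased genes had 1.16 (1.3e-06; adjusted p = 0.817 with an estimated correlation), with 0 of 13 by either count. Without busulfan 3 their median was 2.02, with 13 of 13 past the threshold over all genes and adjusted p = 0.0272 with an estimated correlation. Here too the only busulfan library in which these genes were not low was dropped. Intercalated cell genes had -0.61 (4.8e-04; adjusted p = 0.817 with an estimated correlation) and distal convoluted tubule genes -0.48 (0.00425; adjusted p = 0.817 with an estimated correlation), the latter with 2 of 10 adjusted over the list alone. Without busulfan 3 the medians of these lists were -1.01 and -0.79, with 8 of 12 and 7 of 10 members lower over all genes. Without control 2, 8 lists were called, and 6 calls held with every library left out, these 5 lists and immediate early genes (-0.59).

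L.J. alone against control asked what L.J. did without busulfan. Transcripts typical of liver were lower in the L.J. group: Alb was 21.6 ± 10.5 FPKM in control and 4.41 ± 1.34 with L.J. (log2 change -1.995, SE 0.35, limma adjusted p = 0.215), Apoa1 7.97 ± 5.38 and 1.20 ± 0.41 (adjusted p = 0.225) and Ttr 4.34 ± 2.46 and 0.70 ± 0.22 (adjusted p = 0.347). The pancreas and liver list fell (median -1.73, camera adjusted p = 4.1e-11; adjusted p = 0.203 with an estimated correlation), with 0 of 6 past the threshold over all genes and 5 adjusted over the list alone. By limma 0 genes passed (1 without L.J. alone 3, and 19 with library weights), with 337 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0878, shared by Mup8 (-2.60, SE 0.35), the fatty acid binding protein gene Fabp1 (-2.17) and Mup2 (-3.54). The genes with the smallest p among positive changes were Clu (88.6 ± 5.01 and 129 ± 9.20 FPKM, 0.53, adjusted p = 0.438), Ddit3 (0.65, adjusted p = 0.450) and Stc1 (0.63, adjusted p = 0.489).

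Interferon response genes had a median of 0.31 (camera adjusted p = 2.2e-07; adjusted p = 0.856 with an estimated correlation), with 0 of 22 past the threshold over all genes or adjusted over the list alone. Their medians in L.J. alone 1, 2 and 3 were 0.20, 0.06 and 0.77. Heat shock genes had 0.17 (1.3e-05; adjusted p = 0.856 with an estimated correlation), with Hspa1a at 5.08 ± 4.43 in control and 16.7 ± 11.6 with L.J. (adjusted p = 0.999). Proximal tubule transport genes had 0.16 (1.9e-04; adjusted p = 0.835 with an estimated correlation) and adipocyte genes 0.63 (0.00155; adjusted p = 0.856 with an estimated correlation), the latter with medians of 0.06, 1.61 and 0.35 in the 3 libraries. The remaining calls were glucocorticoid targets (0.20), antigen presentation (0.17), distal convoluted tubule (0.14), thick ascending limb (-0.18), endothelium (-0.22), cholesterol synthesis (-0.23) and principal cell genes (-0.30), each with an adjusted p = 0.856 with an estimated correlation. In these 11 lists 0 members passed over all genes or adjusted over the list alone. Without L.J. alone 1, 7 lists were called, and 5 calls held with every library left out: proximal tubule transport, interferon response, glucocorticoid targets, heat shock, and pancreas and liver. The adipocyte call was lost without L.J. alone 2 (median 0.19, camera adjusted p = 0.126). Among the other lost calls, the distal convoluted tubule median ran from -0.02 to 0.19 with a library left out. That of antigen presentation ran from 0.06 to 0.24 and that of endothelium from -0.38 to -0.03.

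Busulfan plus L.J. against control asked what still differed when both were given. Mup8 fell from 8.64 ± 4.77 to 0.16 ± 0.27 FPKM (n = 3; log2 change -2.98, SE 0.35, limma adjusted p = 0.0300), with 2 of its 3 treated libraries listed at 0. It was the only gene of 12281 to pass, with 352 at an unadjusted p under 0.05. Alb was 5.86 ± 1.17 against 21.6 ± 10.5 (adjusted p = 0.546), and the pancreas and liver list fell (median -1.49, camera adjusted p = 9.3e-11; adjusted p = 0.222 with an estimated correlation), 0 of 6 over all genes and 5 adjusted over the list alone. Among positive changes Ddit3 (7.58 ± 1.00 and 12.6 ± 0.16 FPKM, 0.67, adjusted p = 0.546), Slc38a6 (0.40) and Cant1 (0.34) had the smallest p. Cdkn1a was 9.94 ± 0.53 and 14.7 ± 1.28 FPKM (0.52, SE 0.32, adjusted p = 1.00), and Havcr1 2.08 ± 0.09 and 2.26 ± 0.43 (adjusted p = 1.00).

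The p53 target list, not called with busulfan alone (median 0.20), was called here, with a median of 0.16 (camera adjusted p = 7.3e-05; adjusted p = 0.744 with an estimated correlation) and 0 of 20 past the threshold over all genes or adjusted over the list alone. Phlda3 was 1.91 ± 0.57 and 4.43 ± 0.79 FPKM (0.91, adjusted p = 0.893). Adipocyte genes had a median of 0.89 (7.1e-05; adjusted p = 0.744 with an estimated correlation), and lipogenesis genes, which fat also expresses, 0.32 (0.0307; adjusted p = 0.744 with an estimated correlation), with 0 members past by either count. Acute phase genes had -0.09 (0.0278; adjusted p = 0.744 with an estimated correlation), with 3 of 14 lower adjusted over the list alone. With a library left out this median ran from -0.28 to 0.03. Over the busulfan plus L.J. libraries the acute phase medians ran from -0.80 to 0.26. Proximal tubule transport (0.06), proliferation (0.10), cholesterol synthesis (-0.18), macrophage (-0.21) and endothelial genes (-0.25) were also called, each with 0 members past by either count and adjusted p = 0.744 with an estimated correlation. Mup8 no longer passed when any of the control or busulfan plus L.J. libraries was left out, where 0 genes were called, and without busulfan plus L.J. 2 the lists called were 5. Only the p53 target and the pancreas and liver calls, 2 of 10, held with every library left out.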

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

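Apart from the counts over other splits of the libraries, the tests in this part were chosen after the pattern they weigh was seen; the values of the length and GC test, the direction test on 3973 genes and the second liver list were not known when these were chosen.

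The effect of busulfan differed with L.J. by the interaction test for Wfdc17 (-1.80) and Phlda1 (-0.94), and by camera for 13 lists. Their medians were -0.48 for distal convoluted tubule, -0.61 for intercalated cell, 0.42 for erythroid and blood, 0.19 for proliferation, -0.38 for inflammatory cytokines, -0.49 for interferon response, -0.35 for antigen presentation, -0.62 for glutathione S-transferases, -0.62 for glucocorticoid targets, 1.16 for male-biased kidney genes, -0.59 for immediate early genes, -0.55 for ribosomal proteins and 0.49 for replication-dependent histones. With an estimated correlation 0 of these list calls held, and 6 of the 13 held with every library left out in turn. Without busulfan 3 the calls of antigen presentation (-0.09, camera adjusted p = 0.821) and interferon response (-0.22, 0.881) were lost, and the medians of erythroid and blood, proliferation and inflammatory cytokines were 1.32, 0.39 and -0.62. Of 100 splits drawn, the real one included, 4 gave 2 or more interaction genes, a share under 0.05. The highest other gave 494, which points to a structure of the libraries other than their groups. A split that parts busulfan 1 from busulfan 2 puts their pattern into the spread and leaves few calls by construction. The share therefore does not exclude chance for the 2 genes. Their calls were also lost with a pseudocount of 0.1, quantile normalization, the length and GC correction, or the replicate number as a block. For the lists 41 of the 100 splits gave 13 or more, up to 25, so chance is not excluded for them either.

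With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For busulfan against control 1 of the 10 gave as many genes as the 177 found (highest other 1) and 7 gave as many lists as the 10 found (highest other 24). For busulfan plus L.J. against busulfan 2 of the 10 gave 398 genes or more. The other was busulfan plus L.J. 1 with busulfan 1 and 2 against the rest, with 1962 genes, which points to a structure of the libraries other than their groups; 3 splits gave 17 lists or more (highest other 24). For L.J. alone against control all 10 gave the 0 genes found or more (highest other 1) and 3 gave 12 lists or more (highest other 17). For busulfan plus L.J. against control 1 gave the 1 gene found (highest other 0) and 5 gave 10 lists or more (highest other 17).

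Busulfan 3 stood apart from busulfan 1 and 2, and a bias of length and GC content as the whole cause is argued against by the SD of its log2 difference to busulfan 1, which was 0.541 as deposited and 0.524 after the correction, above the highest pair within the other groups (0.379). The lowest male-biased median in the other groups, -0.16, argues against a swap with a kidney that responded as busulfan 1 and 2 did. It cannot decide on a swap with a control if a kidney given busulfan can lack that fall. A swap with a library given L.J. is argued against by the liver list, at 0.50 in busulfan 3 and -1.82 to -1.45 in those 6. This includes busulfan plus L.J. 1, which followed busulfan 1 and 2 most among the other libraries (67.8% of 3973 genes). An animal that had not received busulfan was not excluded: busulfan 3 followed busulfan 1 and 2 in 47.1% of the 3973 genes (39.4 to 57.7 in the 6 libraries without busulfan, 53.8 and 51.4 in busulfan plus L.J. 2 and 3), and on genes chosen without it that separated the other libraries by busulfan it was nearer the busulfan side for 26.6%. That lay inside the range of held-out libraries without busulfan (18.3 to 36.2), as did busulfan plus L.J. (20.9 to 25.7) but not busulfan 1 and 2 (84.8 and 83.5), so whether a kidney given busulfan alone can score as low stays open. Going the other way, busulfan 3 lay beyond the libraries without busulfan on the busulfan side in 28.9% of the 3973 genes as deposited. Held-out libraries without busulfan had at most 20.1%, and busulfan 3 had 24.3% on the opposite side. After the correction it was 21.5% (at most 21.4, with 23.9 on the opposite side). Cdkn1a was 18.5 FPKM in busulfan 3, against at most 12.04 in libraries without busulfan. All libraries with busulfan lay above that, from 13.33 to 39.28. It is a single gene, although chosen in advance. The p53 target list had a median of 0.01 in busulfan 3, inside the range of L.J. alone (-0.12 to 0.08). Wfdc17 (2.80, at most 1.41) and Phlda1 (11.7, at most 9.26) were also higher in busulfan 3, both called in fits that held it. A missed dose and a variable response thus cannot be told apart. On the first principal component busulfan plus L.J. 1, 2 and 3 (1.9, 10.1 and 10.9) also lay apart from busulfan 1 and 2. Whether something other than the drug set busulfan 1 and 2 apart over all genes was not tested.

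Male-biased kidney genes were low in busulfan 1 and 2. Female animals are argued against by Y-linked genes, the lowest at 86.3% of the control mean in these libraries. Loss of proximal tubule cells as a whole is argued against by the transport list, whose lower median was -0.10 (quartiles -0.59 and 0.26) where the male-biased genes were at -2.16 (-2.60 and -1.76). That list was not unchanged. Without busulfan 3, 5 of its 23 members were higher and 4 lower than in control. Camera placed it down (adjusted p = 0.0236, and 0.582 with an estimated correlation). Its median cannot decide on a loss of only some of these cells. Time of day is argued against by 3 libraries of other groups with Dbp as high, whose lowest male-biased median was -0.04. Reduced androgen signalling is a candidate explanation and a hypothesis, since the lower female-biased median in these libraries was 0.71, although Akr1c14 of that list fell and busulfan 3 and the busulfan plus L.J. libraries lacked the pattern.

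Liver transcripts were lower in all 6 libraries with L.J. Their list median was -1.60 ± 0.16 with L.J. and -0.01 ± 0.50 without (n = 6 each, difference -1.59). Liver tissue or RNA carried into kidneys of the groups without L.J. may be the source: of 20 hepatocyte markers on a second list, 95.0% had lower means in both L.J. comparisons, all but Apoh (8.22 FPKM in control, 10.2 with L.J. alone). Of these 20, however, 11 lay below the filter on low values, and of the 9 above it 8 were lower in both, of which 4 had a log2 change of group means of -1 or below in both, such as Apob (15.95 and 4.43) and Ahsg (4.45 and 0.63), while Serpinc1 (2.23 and 1.86) and others changed little. Handling shared by the L.J. groups cannot be told apart from L.J. itself, since the labels give no collection day.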

How the results depend on the processing

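The length and GC correction, and busulfan 3 left out of fits for comparisons without it, were chosen after seeing the data. Changed genes are given in the order busulfan against control, busulfan plus L.J. against busulfan, L.J. alone against control, busulfan plus L.J. against control, and interaction (177, 398, 0, 1 and 2 as reported). A pseudocount of 0.1 gave 200, 371, 0, 0 and 0. No filter gave 55, 150, 0, 0 and 1. Quantile normalization gave 503, 656, 0, 1 and 0. Library weights (estimated gene by gene, busulfan 3 at 0.11) gave 5240, 4945, 19, 10 and 2422. The length and GC correction gave 3, 0, 0, 1 and 0. Only the groups compared gave 0, 2, 0 and 0, with fewer libraries for the spread. Leaving out each library gave 0 to 3973, 1 to 3867, 0 to 1, 0 to 2 and 0 to 1488, and each highest value but that of L.J. alone came without busulfan 3. By construction a library apart from its group widens the spread shared by all groups. Beyond these points the cause was not tested.

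Called lists (10, 17, 12, 10 and 13 as reported) were 0 in each comparison with an estimated correlation, and 0, 1, 0, 0 and 0 by fry. Library weights gave 19 for busulfan against control. Leaving out each library in turn gave 8 to 22, 15 to 21, 7 to 14, 5 to 14 and 8 to 16 lists. With every library left out in turn 5, 11, 5, 2 and 6 of the calls held. Every other list count stayed within 1.5 times that reported. The interaction median of interferon response lay between -0.67 (without busulfan plus L.J. 1) and -0.22 (without busulfan 3), and in the latter camera placed the list up (adjusted p = 0.881). The correlation of the busulfan effect with and without L.J. ranged from -0.003 (without busulfan 1) to 0.101 with a library left out and was 0.114 with library weights. The share of genes moved back was 98.588% with library weights and 99.390% to 100% with a library left out. That last range covers only 6 left-out libraries, since the share has no value where no gene was called, and some of its values rest on few genes.

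With the replicate number as a block the gene counts were 11, 4, 0, 0 and 0. The labels do not say what a number marks, and same-numbered libraries did not deviate together (18 correlations from -0.239 to 0.081, with 0 above 0.1, and 0 libraries best correlated with their own number), so the libraries share only a number. Of 9508 values of named genes and lists over all settings, 8199 kept their side of the threshold, 856 lost a call, 452 gained one and 1 reversed. Direction was compared only where a fit made a call, and for lists by camera's direction. List medians that turned are therefore not counted. Distal convoluted tubule went to -0.02 for L.J. alone against control, and acute phase to 0.03 for busulfan plus L.J. against control. Depth is unknown, so no limit of detection can be set.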

Other observations

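Clock genes differed within the treated groups, and between these and control. Dbp, a clock output gene, was 45.7 and 35.4 FPKM in busulfan 1 and 2, 41.9 and 40.5 in busulfan plus L.J. 2 and 3, and 37.5 in L.J. alone 2, and lay between 1.65 and 7.62 in the other 7 libraries. These 7 hold all 3 controls, at 1.65 to 2.05. Time of day may thus bear on busulfan against control. It was weighed only for male-biased genes and was not tested for the others. Fat markers differed as well: Adipoq was 35.98 and 18.8 FPKM in busulfan plus L.J. 1 and 2, 22.6 in L.J. alone 2, 13.1 in busulfan 3 and 11.5 in control 3, and was lower in the other 7. The brown fat gene Ucp1 was 8.47, 13.0 and 9.83 in the first 3 of these.

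Genes of the female-biased list did not all go one way in busulfan 1 and 2. Slc7a12 was 22.1 and 34.5 FPKM there and between 1.03 and 2.18 in the other 10 libraries, and Cyp4a14 was 121 and 151 against 1.16 to 3.98. Without busulfan 3, 6 of the 9 tested members were higher and 2 lower than in control. Interferon response medians were 0.71 in busulfan 3, 0.43 in busulfan plus L.J. 1 and 0.77 in L.J. alone 3, and lay between -0.27 and 0.24 in the other 9 libraries.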
